A study of Brassica rapa with 18 samples.

How the data were processed

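Messenger RNA was measured by stranded, paired-end sequencing in leaves of Brassica rapa R-o-18, an inbred line of the variety trilocularis. Per the labels' protocols, seeds were kept at 4 °C for 3 days and seedlings were grown at 22 °C with 16 h of light and 8 h of dark. At an age of 10 days they received 10 mL of spray with 50 µM methyl jasmonate (MeJA), or the same spray without it; both held 0.1% Tween-20. Leaves were frozen at 10 min, 24 h or 72 h, and only RNA with an integrity number above 7 went into libraries. Each of the 6 groups held 3 libraries that the labels call biological replicates, 18 libraries in all.

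The deposited values are raw counts of reads per gene, as whole numbers, which the authors did not normalise. The submitters' processing notes name FastQC, TopHat2, HTSeq and edgeR, without versions or roles. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The table held 42186 features, of which 41018 had identifiers starting with Bra and 1168 had identifiers starting with ENSRNA. No count was found in any library for 5896 features. Counts of genes with near-identical copies, which Brassica rapa has in many families, depend on how reads shared between copies were assigned, and this is unknown here. Overlapping genes are uncertain for the same reason.

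Gene names were sought in the RefSeq gene table of assembly CAAS_Brap_v3.01, with 51589 genes. Only 1 identifier of the count table matched it (Bra000116, given there as a synonym of SWEET9), with a total count of 0 over the 18 libraries. The 31 gene lists written before the data were examined could therefore not be filled, their tests were not run, and genes are given by identifier only.

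Counts were tested with edgeR 4.0.16 in R 4.3.3. Features were filtered by edgeR's filterByExpr on the 6 groups, which left 26593 features, and libraries were scaled by TMM. All 18 libraries entered 1 quasi-likelihood fit of 6 group means, so the groups shared the estimate of spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken from the fold change and the F statistic of its test. It is approximate at low counts. For a difference between responses it is not given where a mock group held at most 3 counts. CPM are counts scaled by library size and TMM factor; log2 CPM used a prior count of 2. Tests compared MeJA with the mock spray at each time, the responses of different times (interaction contrasts) and, for context, the mock libraries over time. Overlaps of calls were tested with Fisher's exact test, two-sided, with 95% confidence intervals. The labels' batch field coincides with the time point, so every comparison of MeJA with mock lies within a batch and every comparison of times also compares batches. No other value column was left unused.

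The named identifiers followed a rule fixed before the data were examined: among genes called at a time, with a mean of at least 1 CPM over its 6 libraries and no overlap between the 3 MeJA and the 3 mock values, the 2 largest rises and the 2 largest falls by fitted log2 fold change. A longer list was planned for named genes only. A fold against a group at 0 is given as a lower bound against a floor of 3 counts over the group. The floor stayed at 3 counts when a library was left out, which by itself lowers a bound where that library belongs to the group at 0. Where the lower group held 1 to 3 counts, the ratio is given with its exact 95% binomial interval. Such intervals and floors cover counting error only, since the reads carry no stated molecular identifiers.

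Library totals ran from 13505607 to 17796115 counts, at which 3 counts amount to 0.222 and 0.169 CPM. Replicate libraries were compared by chi-square over genes with at least 10 counts in a pair. The statistic per degree of freedom ran from 1.49 to 26.9 over 18 pairs, so no pair agreed within sampling noise. The lowest value was that of mock 10 min replicates 2 and 3, and the next lowest was 4.90. A value above 1 does not by itself show that these libraries came from separate plants. The procedure was tested on simulated counts with the sizes of these libraries and 200 genes changed per time, over 25987 genes. Each gene had 1 mean, its average over the mock libraries of the 3 times, and 1 spread for all groups. For 10 min it called 23.1% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 92.2% of those changed 4-fold. For 24 h the shares were 24.6%, 74.6% and 96.9%, and for 72 h they were 20.9%, 57.6% and 93.8%. Unchanged genes called numbered 6, 6 and 9. Spread that differs between groups was not simulated, so these numbers do not show the false calls it could give in the real libraries. Each share rests on 64 to 67 genes and on the same simulated spread, so differences between times do not measure the power at each time.

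Alternatives chosen before the data were examined were DESeq2's size factors, DESeq2 1.42.0's Wald test, no filter beyond a total above 0, a filter of at least 1 CPM in at least 3 libraries, only the libraries of the times compared, a replicate block, a log2 fold change of at least 1, and each library left out in turn. Scaling by library totals alone and thinning all libraries to the lowest total were added after the data were seen, as were all alternatives for the mock libraries over time and all but the fold threshold for the overlaps. Following the genes called at 10 min without MeJA 10 min replicate 2 was added then too.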

Results

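The data were read counts per gene from leaves of Brassica rapa seedlings sprayed with methyl jasmonate (MeJA) or with a mock spray. MeJA is the volatile methyl ester of jasmonic acid, a plant hormone of wounding and defence responses. Harvests followed spraying by 10 min, by 24 h or by 72 h, with 3 biological replicates for each treatment and time. Mean library totals were 13944326 ± 507757 counts (SD, n = 3) for MeJA and 15103061 ± 1088267 for mock at 10 min, 15702484 ± 1687116 and 14955435 ± 491650 at 24 h, and 17267811 ± 127620 and 16876957 ± 1017615 at 72 h. The question was how the leaf transcriptome differed between MeJA and mock at each time. The gene identifiers could not be paired with names, so genes are described by identifier and by the time and direction of their change.

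The first principal component of log2 CPM held 42.3% of the variance and separated the MeJA libraries from the mock libraries of the same time at every time. The MeJA libraries of 24 h lay between 82.6 and 105.5 on this component, and the mock libraries of 24 h between -37.3 and -12.9. The second component held 16.8% of the variance. On it, MeJA 10 min replicate 2 lay at 66.7, apart from replicates 1 and 3 at 27.4 and 28.6.

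**Figure D1:**
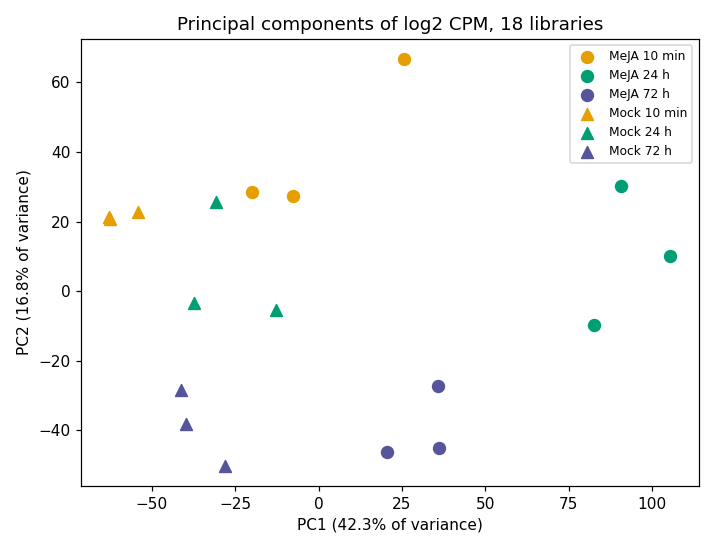
Each point is 1 of the 18 libraries, placed by its first (x axis, 42.3% of variance) and second (y axis, 16.8%) principal component of log2 CPM; circles are MeJA and triangles mock, coloured by time. The 3 MeJA 24 h libraries lie farthest right, between 82.6 and 105.5, and MeJA 10 min replicate 2 lies highest, at 66.7.

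At 10 min, 1248 genes were higher and 647 lower with MeJA than with mock, of 26593 tested. The rises were larger than the falls: the median log2 fold change was 1.14 among genes that rose and -0.54 among genes that fell. Of the genes that rose, 35 had at most 3 counts over the 3 mock libraries. The largest rise by the naming rule was Bra001453, at 47.95 ± 51.9 CPM (SD, n = 3) with MeJA and 0.0866 ± 0.0751 CPM with mock, a log2 fold change of 8.95 (SE 1.19; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00133). Its counts were 108, 1601 and 416 in the MeJA libraries, and its log2 fold change was 7.59 without MeJA replicate 2. Bra035844 had no count in the mock libraries and 3.65 ± 2.19 CPM (SD, n = 3) with MeJA, at least 54.6-fold higher (edgeR adjusted p = 0.00459) and at least 35.1-fold without mock replicate 2.

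The largest falls at 10 min by the same rule were much smaller than these rises. Bra021523 stood at 0.623 ± 0.315 CPM (SD, n = 3) with MeJA and 2.42 ± 0.429 CPM with mock, a log2 fold change of -1.95 (SE 0.43; edgeR adjusted p = 0.0131). Bra004148 stood at 0.493 ± 0.387 and 1.66 ± 0.611 CPM, a log2 fold change of -1.75 (SE 0.50; edgeR adjusted p = 0.0434). The call of Bra021523 was lost without MeJA replicate 2 or mock replicate 2 (adjusted p = 0.0847 and 0.0664). That of Bra004148 was lost in 6 of 14 alternatives, among them without MeJA replicate 1 or 2 and without mock replicate 2 or 3. Its adjusted p ranged from 0.00892 to 0.211 over all of them, and its log2 fold change was -2.59 without MeJA replicate 3.

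Replicate 2 of MeJA 10 min carried more of the transcripts that were abundant 24 h after MeJA. Over 22 genes with at least 50 CPM in MeJA 24 h and under 0.2% of that level in mock 10 min, the median level relative to MeJA 24 h was 3.96% in replicate 2, 0.239% in replicate 1 and 0.357% in replicate 3. ENSRNA identifiers also took more of the counts in replicate 2, 4.31% against 1.35% in replicate 1 and 1.77% in replicate 3. Without MeJA replicate 2, 411 genes were called at 10 min in place of 1895, and 407 of them were among the 1895. The count was 1231 without mock replicate 1, 358 without mock replicate 2 and 447 without mock replicate 3. Mock 10 min replicates 2 and 3 were also the replicate libraries that agreed most closely, at a chi-square of 1.49 per degree of freedom. The 10 min tests treat them as independent, which was not tested. Rises made up 65.9% of the calls under TMM and 85.7% when libraries were scaled by their totals alone.

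At 24 h, 4098 genes were higher and 3490 lower with MeJA, 28.5% of the genes tested. Median log2 fold changes were 0.76 among genes that rose and -0.69 among genes that fell. Genes that rose held 27.8% ± 2.69 of the counts in the MeJA libraries (SD, n = 3) and 12.3% ± 0.553 in the mock libraries. Bra000129 was among the most strongly raised, at 972.7 ± 295.1 CPM (SD, n = 3) with MeJA and 0.369 ± 0.329 CPM with mock, a log2 fold change of 11.35 (SE 1.096; edgeR adjusted p = 1.34e-06) and of 12.25 without mock replicate 2. Bra035814 had no count in any mock library and 23.2 ± 11.7 CPM (SD, n = 3) with MeJA, at least 366-fold higher (edgeR adjusted p = 1.58e-05) and at least 240.0-fold without mock replicate 1.

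At 24 h, 21 of the genes that fell had at most 3 counts over the 3 MeJA libraries. Bra006412 had 1 count over the MeJA libraries, in replicate 1, and 111 over the mock libraries, 107-fold lower (95% interval 18.7 to 4248; edgeR adjusted p = 0.000186). It was at least 24.1-fold lower without MeJA replicate 1, and the ratio was 68.1 without MeJA replicate 3. Bra022267 had 2 and 120 counts, 57.6-fold lower (95% interval 15.6 to 481; edgeR adjusted p = 0.000388). In mock libraries these genes stood at 2.35 ± 1.68 and 2.57 ± 1.33 CPM (SD, n = 3). Without MeJA replicate 3, 5026 genes were called at 24 h, and with only the 24 h libraries in the fit, 4818. Under scaling by library totals the larger direction turned: rises were 33.7% of the calls in place of 54.0%, and the median log2 fold change of all genes moved from -0.01 to -0.13.

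At 72 h, 1625 genes were higher and 964 lower with MeJA. Median log2 fold changes were 0.81 among genes that rose and -0.61 among genes that fell. Bra016073 had 1 count over the 3 mock libraries, in replicate 1, and 1286 over the MeJA libraries (24.8 ± 5.25 CPM; SD, n = 3), a ratio of 1221 (95% interval 219 to 48259; edgeR adjusted p = 0.000852). Bra000129 was again among the largest rises, with 1 count in mock libraries, in replicate 1 too, and 913 in MeJA libraries (17.6 ± 5.76 CPM; SD, n = 3), a ratio of 867 (95% interval 155 to 34272; edgeR adjusted p = 0.00244). Without mock replicate 1 these were at least 265.9-fold and at least 188.7-fold higher, and without mock replicate 2 the ratios were 804.3 and 571.0. At 24 h Bra016073 stood at 712.9 ± 203.7 CPM with MeJA and 0.407 ± 0.101 CPM with mock (SD, n = 3). Whether the responses of Bra016073 and Bra000129 differed between 24 h and 72 h could not be decided (edgeR adjusted p = 0.981 and 0.947). At 24 h and 72 h the mock libraries held only 19 and 1 counts of Bra016073 and 17 and 1 of Bra000129. At such counts the test gives no usable SE for the difference.

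Among the falls at 72 h, Bra031773 had no count in the MeJA libraries and 9.14 ± 9.39 CPM (SD, n = 3) in mock, at least 163-fold lower (edgeR adjusted p = 0.0339). The bound was 77.8 without mock replicate 2, where the mock mean was 4.28 CPM, and 107.9 and 108.1 without MeJA replicate 1 or 2. Bra024932 stood at 0.233 ± 0.213 CPM (SD, n = 3) with MeJA and 9.95 ± 8.15 CPM with mock, a log2 fold change of -5.39 (SE 1.24; edgeR adjusted p = 0.0120) and of -6.34 without MeJA replicate 3. Both were low in mock 72 h replicate 3, with 2 and 10 counts, against 144 and 227 in replicate 1 and 317 and 267 in replicate 2. The call of Bra031773 was lost on leaving out any library of this comparison except mock replicate 3 (highest adjusted p = 0.125), and that of Bra024932 without MeJA replicate 1 or 2 (adjusted p = 0.0580 and 0.0615). The count of genes called at 72 h, 2589, was 1166 without MeJA replicate 1, 1023 without MeJA replicate 2, 1400 without mock replicate 1 and 1188 without mock replicate 2. Rises were 62.8% of the calls, and 74.1% under scaling by library totals. ENSRNA identifiers took 3.23% ± 1.34 of the counts in MeJA and 5.14% ± 0.691 in mock libraries at 72 h (SD, n = 3), and 8 of the 71 tested fell.

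**Figure D2:**
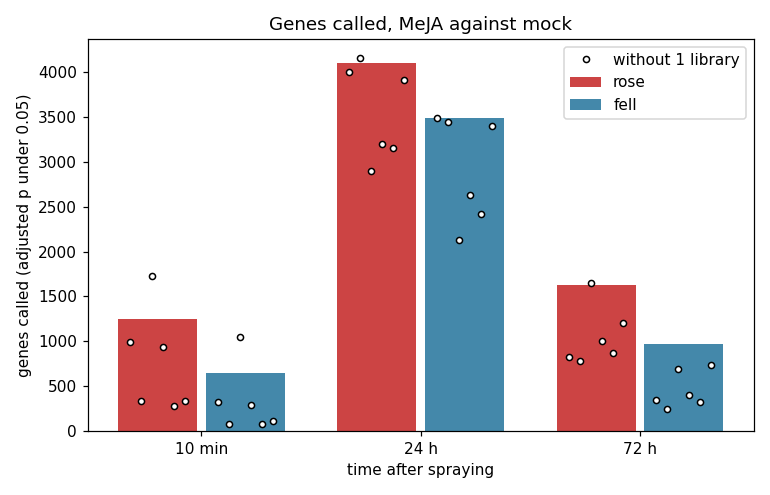
Bars give the number of genes called (y axis; edgeR adjusted p under 0.05) as higher or lower with MeJA than with mock at each time (x axis); open circles give the number when 1 of the 6 libraries is left out. Calls were most numerous at 24 h, with 4098 rises and 3490 falls.

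**Figure D3:**
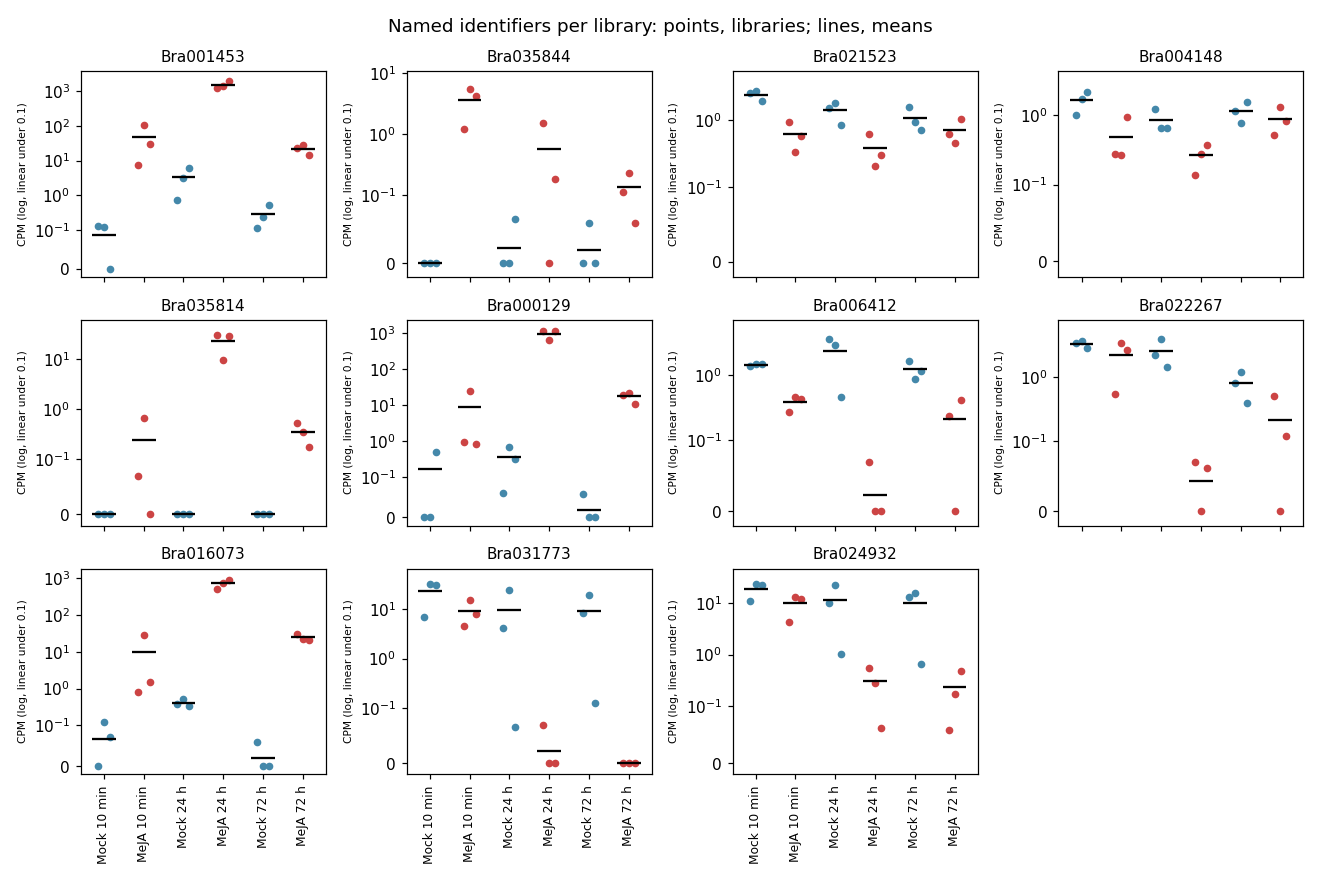
Each panel is 1 named identifier; points are libraries, lines are means of 3 libraries, red is MeJA and blue is mock, and the y axis is CPM on a log scale that is linear under 0.1. Bra000129 and Bra016073 reached 972.7 and 712.9 CPM on average in MeJA 24 h, and Bra031773 and Bra024932 were low in 1 mock library of 24 h and of 72 h.

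The same genes were called at different times far more often than independent lists would share. Of the rises, 927 were shared by 10 min and 24 h where 192 would be shared by independent lists, with an odds ratio of 20.2 (95% interval 17.7 to 23.1; Fisher's exact test). For 24 h and 72 h, 1214 rises were shared against 250.4 for independent lists, with an odds ratio of 22.6 (95% interval 20.1 to 25.5). Falls were shared by 400 genes between 10 min and 24 h (odds ratio 11.97, 95% interval 10.1 to 14.2) and by 610 between 24 h and 72 h (odds ratio 13.6, 95% interval 11.9 to 15.6). The overlap was smallest for falls at 10 min and 72 h, with 103 genes against 23.5 for independent lists and an odds ratio of 5.52 (95% interval 4.38 to 6.90). Without MeJA 10 min replicate 2, 261 rises (odds ratio 20.3) and 60 falls (odds ratio 23.2) were shared by 10 min and 24 h. Without mock 10 min replicate 2 these were 217 (odds ratio 22.6) and 59 (odds ratio 18.9), and without mock 10 min replicate 3 they were 260 (odds ratio 21.6) and 82 (odds ratio 20.3). Falls shared by these times numbered 230 without MeJA 10 min replicate 1, 183 without mock 10 min replicate 1 and 250 without MeJA 24 h replicate 3. Without MeJA 72 h replicate 1 or 2 or mock 72 h replicate 1 or 2, 24 h and 72 h shared 640 to 719 rises and 169 to 235 falls. Falls shared by 10 min and 72 h ran from 13 without mock 10 min replicate 2 to 146 without MeJA 10 min replicate 3. Over all libraries left out in turn, the odds ratio ran from 15.6 to 23.5 for rises and from 9.21 to 23.2 for falls at 10 min and 24 h, from 17.3 to 31.3 and from 8.21 to 22.2 at 24 h and 72 h, and from 4.99 to 11.6 for falls at 10 min and 72 h. Among the other alternatives the odds ratios were highest at a log2 fold change of at least 1, except for rises at 10 min and 24 h, which gave 34.4 there and 34.7 by DESeq2. At that threshold they were 65.1 for rises and 66.7 for falls at 24 h and 72 h, 48.6 for falls at 10 min and 24 h, and 47.1 for rises and 13.5 for falls at 10 min and 72 h. Each time had its own mock libraries, so no control was shared between these lists. The lists did share 1 fit and its estimate of spread, and abundant genes were called more often at every time. Some sharing beyond that of independent lists would follow from this alone. Fisher's intervals also treat genes as independent of each other.

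Genes called at one time mostly leaned the same way at the others. The 1248 genes that rose at 10 min had a median log2 fold change of 1.01 at 24 h and 0.79 at 72 h, and 1222 of them were above 0 at 24 h. The 647 genes that fell at 10 min had medians of -0.47 and -0.18. Both sets shrank without MeJA 10 min replicate 2, the library with more of the transcripts abundant in MeJA 24 h. They also shrank to 276 rises and 82 falls without mock 10 min replicate 2, and to 335 and 112 without mock 10 min replicate 3. Without MeJA 10 min replicate 2, 334 rises and 77 falls were called, with medians of 1.102 at 24 h and 0.99 at 72 h for 332 of the rises and of -0.59 and -0.21 for the falls. The 4098 genes that rose at 24 h had medians of 0.31 at 10 min and 0.35 at 72 h. With genes at 0 counts in a group set to their bound, these 2 medians were 0.31 and 0.35 again. The median at 10 min was 0.24 without MeJA 10 min replicate 2, and 0.23 with such genes set to their bound. Values at the time a set was chosen are inflated by that choice.

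**Figure D4:**
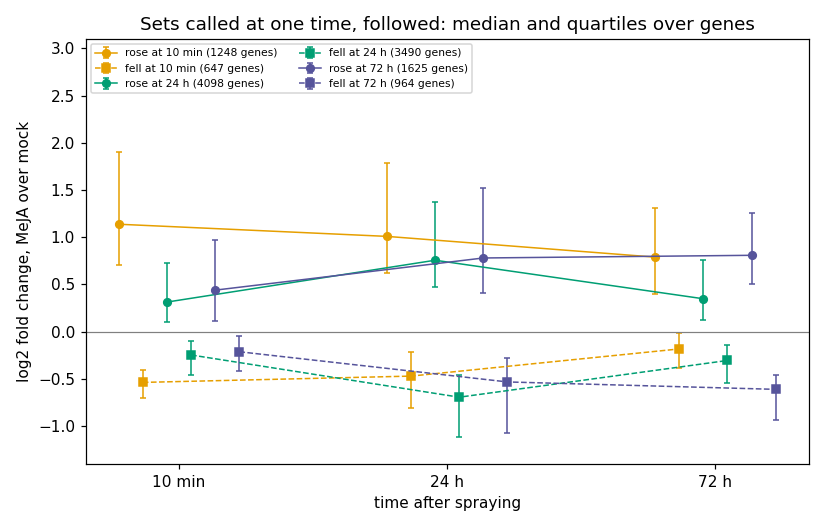
Points are median log2 fold changes (y axis, MeJA over mock) at each time (x axis) of genes called at 1 time, and bars span the quartiles over genes; solid lines are genes that rose and dashed lines genes that fell. Genes that rose at 10 min had medians of 1.14, 1.01 and 0.79 at the 3 times.

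The change in the response between times was tested directly. From 10 min to 24 h, the fold change over mock became more positive in 535 genes and more negative in 232. Bra022267, named above for its fall at 24 h, was among the latter, at 2.23 ± 1.51 CPM with MeJA and 3.33 ± 0.424 CPM with mock at 10 min (SD, n = 3), and its log2 response at 24 h differed from that at 10 min by -5.04 (SE 1.203; edgeR adjusted p = 0.0297). This call was lost in 6 of 20 alternatives, namely without MeJA 10 min replicate 3, MeJA 24 h replicate 3, mock 10 min replicate 1, 2 or 3, or mock 24 h replicate 2, and its adjusted p ranged from 0.00422 (DESeq2) to 0.0944 (edgeR). From 24 h to 72 h, 173 genes became more positive and 312 more negative. Between 10 min and 72 h, 70 became more positive and 10 more negative. The larger direction turned in both comparisons with 24 h under scaling by library totals, with 333 genes more positive and 1243 more negative for 24 h minus 10 min, and 565 and 187 for 72 h minus 24 h. Leaving out 1 library moved these counts by over 1.5 times for 8, 10 and 10 of the 12 libraries of each test. The counts ranged from 316 (without MeJA 24 h replicate 3) to 1573 (without MeJA 24 h replicate 2) for 24 h minus 10 min, from 132 (without MeJA 24 h replicate 3) to 1015 (without MeJA 24 h replicate 1) for 72 h minus 24 h, and from 17 (without mock 10 min replicate 2) to 123 (without MeJA 10 min replicate 3) for 72 h minus 10 min.

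The mock libraries also differed between times, which here coincide with plant age and the labels' batch. From 10 min to 24 h, 682 genes were higher and 979 lower in mock, and from 24 h to 72 h, 443 were higher and 527 lower. Under scaling by library totals the larger direction of the first turned, with 1255 genes higher and 522 lower, and the second gave 245 and 1475. It also turned for the first at a log2 fold change of at least 1, with 174 genes higher and 114 lower, and for the second without mock 72 h replicate 3, with 173 and 152. The 443 included 39 of the 71 ENSRNA identifiers tested. Leaving out single libraries gave 530 (without mock 24 h replicate 3) to 1620 genes for the first of these comparisons and 267 (without mock 24 h replicate 2) to 827 for the second.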

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

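Of the tests below, the one of mixing and its rule, and the breakdown of the regrouped libraries by the number exchanged, were chosen after the result was seen, and thinning the libraries was added after the data were seen. Groups of 3 libraries were not tested for a single outlying library.

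The response to MeJA differed between times by the interaction test for 767 genes between 10 min and 24 h, for 485 between 24 h and 72 h and for 80 between 10 min and 72 h. Among the named identifiers this held for Bra022267, whose log2 response at 24 h differed from that at 10 min by -5.04, a call lost in 6 of 20 alternatives, namely without MeJA 10 min replicate 3, MeJA 24 h replicate 3, any mock 10 min replicate or mock 24 h replicate 2 (adjusted p from 0.00422 by DESeq2 to 0.0944 by edgeR). When time labels were regrouped within each treatment, 11 of 100 splits gave at least 767 genes, 6 of 100 at least 485 and 9 of 100 at least 80, the real ones included. The highest other counts, 8368, 1690 and 10419, were far above the real ones and point to a structure of the samples. Each of the other splits that reached the real count exchanged different numbers of MeJA and mock libraries, so that a change over time shared by both treatments entered the contrast. These splits therefore do not measure chance for a difference in response, and whether chance can be excluded stays open. Among splits that exchanged equal numbers, the highest counts were 7, 0 and 0, over 38, 41 and 35 splits. Each of these mixed libraries of 2 times within groups, which widens the spread, so low counts there do not measure chance either.

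More genes were called at 24 h (7588) than at 10 min (1895) or 72 h (2589). A difference in depth was argued against, since with all libraries thinned to 13505607 counts the 24 h count was still 3.04 times the higher of the others. A smaller spread between replicates at 24 h was argued against too: the variance of log2 fold changes less the part from replicate spread was 2.43 times the higher of the others, and the median SD of MeJA libraries was 0.171 at 24 h against 0.135 at 10 min and 0.108 at 72 h. The median SD of mock libraries was also highest at 24 h, at 0.131 against 0.084 at 10 min and 0.109 at 72 h. The main fit shared 1 estimate of spread over all groups, which can understate the spread at 24 h and so raise its count. The excess was smaller, with 4818 genes at 24 h, 3709 at 72 h and 1324 at 10 min, when each time was fitted on its own libraries. How much of the excess came from the shared estimate was not tested. The time after spraying and the labels' batch coincide, so they cannot be told apart as sources. The 10 splits of 6 libraries are too few for a share under 0.05. Only 1, the real split, reached the real count in each comparison, and the highest other counts were 0 at 10 min, 1 at 24 h and 124 at 72 h. Every other split put MeJA and mock libraries in 1 group, which widens the spread, so these low counts do not measure chance.

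MeJA 10 min replicate 2 held more of the transcripts abundant in MeJA 24 h than replicates 1 and 3. Mixing with a MeJA 24 h library would give these 22 genes 1 common share. For each of 3 possible donors, 3 genes lay further below the median share than any did in 6 comparisons of MeJA 24 h libraries with each other (lowest log2 -1.50), 1 of them at no more than 3 counts. The lower quartile over the genes, from -0.63 to -0.43, lay within that range. The verdict turns on the rule, so mixing stays open. A rule that allows no gene beyond the range would exclude mixing at 1 share, and one on the lower quartile does not. In replicate 2 the 22 genes ran from 0% to 16.5% of their level in MeJA 24 h. The range between MeJA 24 h libraries also holds differences beyond counting error, so it is lenient for reads mixed in from 1 of them. An earlier test on counting error alone had excluded mixing and was replaced by this one. A 72 h library under a 10 min label was argued against by 486 genes that differed between mock 10 min and mock 72 h and had no MeJA call: on a scale from 0 (mock 10 min) to 1 (mock 72 h), replicate 2 lay at a median of 0.0818, and replicates 1 and 3 at 0.213 and 0.156. ENSRNA identifiers took 4.31% of the counts in replicate 2, against 1.35% and 1.77% in replicates 1 and 3. In the MeJA 24 h libraries they took 1.47% to 2.38%, so mixing would not by itself account for the higher share. This share varied within other groups too, from 1.69% to 4.03% in MeJA 72 h. The labels give no group that separates replicate 2 from the others, so no biological explanation was tested.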

How the results depend on the processing

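The scaling by library totals, the thinning and most alternatives for the overlaps and the mock libraries were chosen after the data were seen. All 126 alternatives for the 6 overlaps, each library of the times compared left out in turn included, kept an odds ratio above 1 past the threshold, from 4.99 to 66.7. All 186 alternatives run for the 13 results of named identifiers kept their direction and 165 kept the call. Of the 13, 8 kept it in every alternative that was run. Bra006412 at 24 h, among these 8, and Bra031773 at 72 h had no result with only the libraries of the times compared. Requiring a log2 fold change of at least 1 left 776, 2522 and 827 genes at the 3 times in order, 425, 273 and 53 for the differences 24 h minus 10 min, 72 h minus 24 h and 72 h minus 10 min, and 288 and 285 for the mock libraries over time; fewer genes pass by construction. The DESeq2 Wald test gave 1312, 949 and 460 for the differences and 1594 for mock 72 h minus 24 h. Library totals gave 1576 for 24 h minus 10 min (333 more positive, 1243 more negative) and 752 for 72 h minus 24 h (565 and 187), both with the larger direction turned. They gave 1777 for mock 24 h minus 10 min (1255 higher, 522 lower), turned too, and 1720 for mock 72 h minus 24 h (245 and 1475). Fitting only the libraries of the times compared gave 1324 at 10 min, 4818 at 24 h, 3709 at 72 h, 377 for 24 h minus 10 min, 375 for 72 h minus 10 min, and 960 and 609 for the mock comparisons. Apart from the fold threshold, the cause was not tested. Leaving out 1 library gave 358 to 2769 genes at 10 min, 5026 to 7612 at 24 h, 1023 to 2344 at 72 h, 316 to 1573, 132 to 1015 and 17 to 123 for the differences, and 530 to 1620 and 267 to 827 for the mock comparisons. With the replicate block, 1801, 7406 and 2728 genes were called at the 3 times and 861, 482 and 79 for the differences. No clear pairing by replicate number was seen, though so few libraries cannot exclude it. Correlations of same-numbered libraries ran from -0.215 to 0.287, and 4 of 9 MeJA libraries correlated best with their own number. This block lies within a time; with the replicate number as a replicate block across times, chosen after the data were seen, 1358 and 768 genes were called for the mock comparisons. The gene list tests, and their alternatives, were not run because identifiers had no names. Of genes under 1 CPM, 3.27%, 14.97% and 2.58% were called at the 3 times, against 12.97%, 46.1% and 17.95% of genes over 100 CPM; whether depth sets this difference was not tested.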

Other observations

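The test of mock plants and the genes called without MeJA 10 min replicate 2 in this part were chosen after the result was seen. The share of the counts held by the 1248 genes that rose at 10 min was highest at 24 h among the MeJA libraries: 4.30% ± 1.52 (SD, n = 3) in MeJA 10 min, 11.6% ± 1.52 in MeJA 24 h and 4.08% ± 0.462 in MeJA 72 h, against 1.99% ± 0.100, 2.40% ± 0.249 and 1.91% ± 0.133 in the mock libraries of these times. Most of these calls were lost without MeJA 10 min replicate 2, for which mixing with a MeJA 24 h library stays open. A similar loss followed without mock 10 min replicate 2 or 3, with 276 and 335 rises called, so it was not particular to that library. The 334 genes that rose without MeJA 10 min replicate 2 held 1.03% ± 0.0462 in MeJA 10 min (SD, n = 2), 6.94% ± 1.01 in MeJA 24 h and 1.498% ± 0.189 in MeJA 72 h (SD, n = 3). Bra001453, named at 10 min, reached 1525 ± 346.5 CPM in MeJA 24 h and stood at 21.9 ± 7.15 CPM in MeJA 72 h (SD, n = 3). In mock it stood at 0.0866 ± 0.0751, 3.39 ± 2.78 and 0.292 ± 0.207 CPM at the 3 times. Its responses were not found to differ (edgeR adjusted p = 0.978 for 24 h minus 10 min and 0.580 for 72 h minus 24 h). The SEs of these differences were 1.36 and 1.95 log2 units, so sizeable differences could have been missed. Bra035844 stood at 3.65 ± 2.19 CPM in MeJA 10 min, 0.571 ± 0.834 in MeJA 24 h and 0.134 ± 0.0874 in MeJA 72 h (SD, n = 3). The differences between its responses did not pass the test (edgeR adjusted p = 0.630 for 24 h minus 10 min and 0.585 for 72 h minus 10 min). The mock libraries held 0, 1 and 1 counts of it at the 3 times, too few for a usable SE of these differences or to decide.

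Mock 24 h differed from mock 10 min in the direction of the MeJA response. Genes called at 72 h had a median log2 change from mock 10 min to mock 24 h of 0.07 where they rose and -0.09 where they fell, a difference of 0.160. Their contrast compares neither mock group, though both entered the fit that set the filter, the scaling and the spread. A candidate explanation is that MeJA, which is volatile, reached mock plants. The difference is also what a change with time of harvest or batch could give, and 56.7% of the genes that rose at 72 h were higher in mock 24 h against 51.4% of all genes, so these explanations cannot be told apart here. For the mock libraries over time, the highest other of 10 splits called 0 genes in both comparisons, against 1661 and 970, and 10 splits are too few for a share under 0.05.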
